A study of Mus musculus with 8 samples.

How the data were processed

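Gene expression was measured in 4 kinds of mouse male germ cell with 8 oligonucleotide arrays of the type Mouse 430 2.0, named in the labels' description. The groups were type A spermatogonia, type B spermatogonia, pachytene spermatocytes and round spermatids, with 2 arrays each. Per the labels, the RNA was total RNA from mice of mixed BL/6-129 background. Per the series' design text, each array came from a separate germ cell preparation. The p-values of single genes therefore measure the spread between preparations, pooled over the 4 groups. The camera p-values of gene lists and of X-linked genes at a preset correlation compare genes with other genes. They do not measure that spread. How the cells were purified, and how pure each preparation was, is not given in the sources used here.

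The authors deposited 1 intensity value per probe set and array on a linear scale, made with MAS5 per the submitters' processing notes. The MAS5 version, its detection calls and the array annotation build are not given in the sources used here. The deposited intensities had been scaled between arrays. Without the lowest and highest 2% of probe sets, the mean intensity was 125 on each of the 8 arrays. This scaling sets the average signal equal, so a change of total RNA per cell is not visible and each change is relative to the rest of the array. The median signal ran from 33.7 to 51.9. The number of arrays limits the precision of every value.

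Probe sets were named from the platform annotation and updated through Entrez identifiers with a GRCm38.p6 gene table, used only for names and for the chromosome of each gene. Of 45101 probe sets, 64 were controls, 34945 listed exactly 1 gene, 932 listed several and 9160 listed none. Of those with 1 gene, 34741 matched the gene table and 204 did not. No gene was named from a probe set with several genes. Each of the 18193 genes was represented by its probe set with the highest mean over the 8 arrays. A gene was tested when that probe set lay above the median of its array on at least 2 of 8 arrays, whatever the group. This left 14145 genes, of which 477 were X-linked, 8 Y-linked and 13579 autosomal. Where a called gene had several probe sets, all of them had the same sign for 83.5% of genes between type B and pachytene cells, 71.1% between pachytene cells and spermatids, and 74.7% between type B cells and spermatids.

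Values were analysed as log2(signal + 16). A fold change on this scale understates the change of a gene with low signal. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit with 1 mean per group over all 8 arrays, then eBayes without trend). The fit had 4 residual degrees of freedom and a prior of 4.04. Tests were two-sided, Benjamini-Hochberg adjusted within each comparison, and called at an adjusted p under 0.05. The 4 comparisons were type B against type A, pachytene against type B, spermatids against pachytene, and spermatids against type B. In the text, ± after a log2 change is the standard error of that fit, with n = 2 arrays against 2. The fit shares its spread over all 4 groups. A gap between the replicates of any group therefore widens the ± in every comparison, also in those without that group. For X-linked genes, the median log2 change minus that of autosomal genes was tested with camera from limma at a preset correlation of 0.01 and adjusted over the 4 comparisons. The same level on each array was compared by an exact permutation test over all ways to split 8 arrays into 4 pairs, because 2 arrays against 2 cannot go below p = 0.333.

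The comparisons, the settings, the rule for named genes and 22 gene lists were fixed before the data were examined. The lists, written from textbook knowledge, held undifferentiated spermatogonia, differentiating spermatogonia, DNA replication and mitosis, meiotic chromosome axis and recombination, pachytene spermatocyte, piRNA pathway, spermatid acrosome and flagellum, spermatid chromatin packaging, sex body factors, X-linked housekeeping, X-linked spermatogonial, X-linked spermatid, Y-linked, autosomal retrogenes of X-linked parents, X-linked parents of retrogenes, somatic glycolysis, sperm-specific glycolysis, Sertoli cell, Leydig cell, peritubular, stromal and endothelial cell, macrophage and blood cell, and autosomal cytosolic ribosomal proteins. Some genes are in several lists. Each list was tested in each comparison with camera, which compares its members with all other genes, and the 88 tests were adjusted together. With an estimated correlation in place of the preset value, no list and no X-linked comparison stayed under an adjusted p of 0.05. That correlation was estimated once per list from the spread within all 4 groups, such as 0.68 for spermatid acrosome and flagellum. The gap between the type B replicates therefore enters it in every comparison, also in those without type B. The fry test of limma, which asks whether the genes of a list move on balance one way and does not compare them with other genes, gave 46 of the 88. For X-linked genes its unadjusted p was 0.480, 4.69e-05, 0.00209 and 4.12e-04 in the 4 comparisons, in the order given above.

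The rule named, per comparison, the 5 largest rises and falls among called genes whose arrays did not overlap between groups. It also named, of each list, up to 4 called members with the largest change and up to 2 with the highest signal that did not pass. It further took the 5 largest X-linked rises and falls and every Y-linked, retrogene, parent, sperm-specific glycolysis and chromatin packaging gene. The text prints a selection of the genes so named, made after their values were seen. In the comparison of type B with type A it also names 9 genes outside the rule.

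The test was checked on simulated arrays of the 14145 genes in each comparison, with 100 genes changed 2-fold and 100 changed 4-fold. Of the 2-fold changes, 24% were called between type A and type B, 22% between type B and pachytene cells, 13% between pachytene cells and spermatids, and 32% between type B cells and spermatids. Of the 4-fold changes the shares were 98%, 94%, 93% and 95%. Unchanged genes called numbered 8, 7, 6 and 5. Far fewer genes changed in the simulation than were called in the comparisons with pachytene cells or spermatids, and its noise was independent between genes. Its adjusted threshold was therefore stricter, and the shares called do not carry over to those comparisons. For each gene the simulated noise had 1 SD for all 4 groups. On the real arrays the SD of the replicate difference was 0.751 in type B, against 0.429, 0.338 and 0.335 in the other groups. The shares therefore do not carry over to type B against type A either, and a lack of calls there does not exclude large changes. A simulated X-linked shift of -1 came back as -1.02, -0.96, -1.01 and -1.01, which checks the calculation only.

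Alternatives were pseudocounts of 1 and 64, no filter, a filter at the 75th percentile, quantile normalization, centring on the 75th percentile or on ribosomal protein genes, trend and robust eBayes, a fit of the compared groups alone, the mean of all probe sets of a gene, no probe sets whose identifier marks possible cross-matching, every probe set, a 2-fold limit, other X-linked and autosomal gene sets, the replicate number as a block, and leaving out each array. Type A in place of type B, and a crossed block, were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.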

Results

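Transcript levels were compared across 4 stages of mouse spermatogenesis. Type A and type B spermatogonia are the dividing cells before meiosis, pachytene spermatocytes are in the prophase of the first meiotic division, and round spermatids are the haploid cells that follow meiosis. Each stage was measured on 2 arrays from separate cell preparations, 8 arrays in all, and 14145 genes were tested. Median signal was 41.5 to 51.9 on the spermatogonial arrays and 33.7 to 37.3 on the later ones.

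Across genes, which are not independent replicates, the log2 signals of the replicates correlated at r = 0.962 in type A, 0.980 in pachytene, 0.981 in spermatids and 0.886 in type B. Type B replicate 1 correlated with type A replicate 1 and 2 at 0.957 and 0.975, above its value with type B replicate 2 and, for the second, above that of the type A pair. The SD of the replicate difference was 0.751 in type B against 0.429, 0.338 and 0.335 in type A, pachytene cells and spermatids. Type B replicate 2 read high for genes of later stages. Ldhc, the lactate dehydrogenase of germ cells, had a signal of 4896 in type B replicate 2 and 28.3 in replicate 1, against 5975 and 6563 in the pachytene arrays. These 2 pachytene values were the highest of any probe set on their arrays, so a limit of the scale may hide part of the gap. Over 634 genes that are high in later stages, the excess of replicate 2 was 21.1% of the pachytene excess at the median. Tnp1, a transition protein that packs spermatid chromatin, read 246.6 in replicate 2 and 1.5 in replicate 1, against 3037 and 4397 in spermatids. The 18S ribosomal RNA control at its 3′ end ran from 2658 to 3450 on the spermatogonial arrays and from 120.1 to 276.3 on the later ones. This split runs along the pachytene and spermatid comparisons with type B, so a difference in labelling or hybridization between these arrays, if there was any, cannot be told apart from the stage there.

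**Figure D1:**
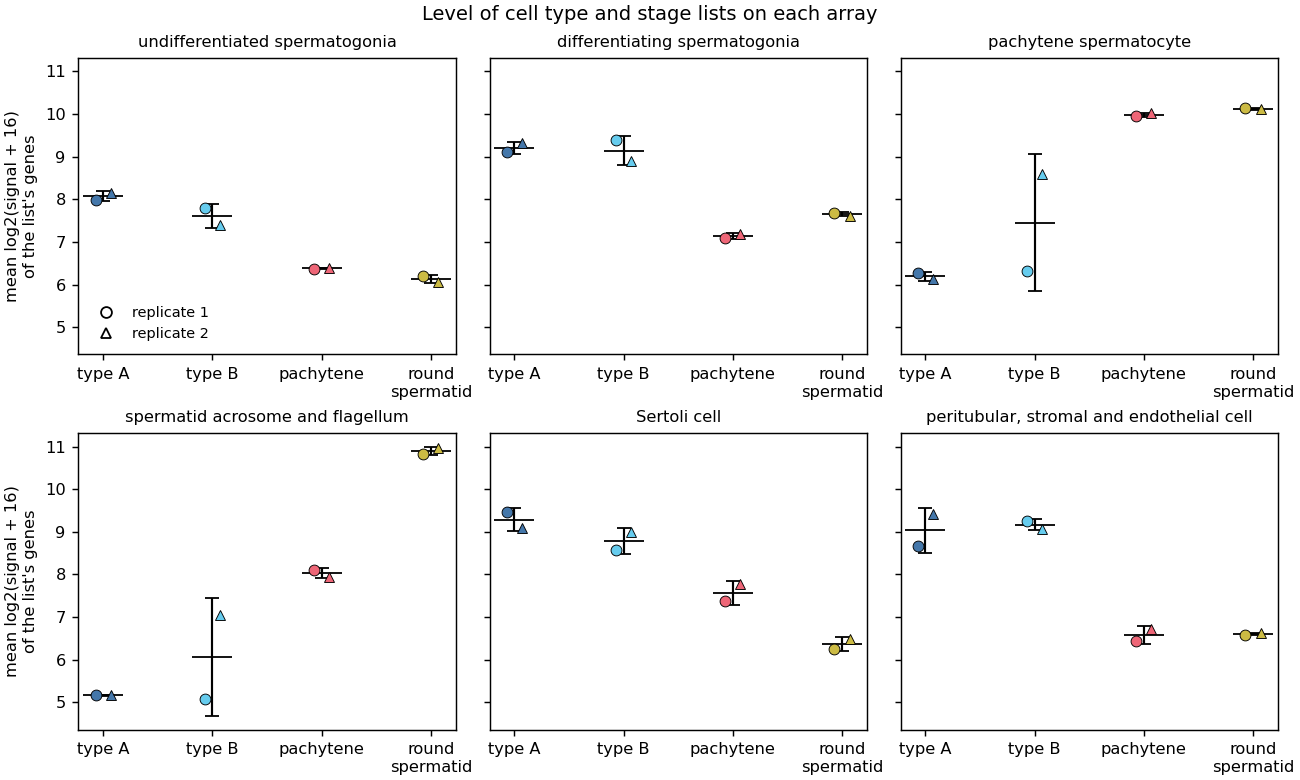
Mean log2(signal + 16) of the genes of 6 lists on each array, by stage, with replicate 1 as circles, replicate 2 as triangles, and the bar and whiskers the mean ± SD of 2 arrays. The pachytene spermatocyte list stood at 7.45 ± 1.61 in type B, where the replicates lay far apart, and at 9.99 ± 0.05 in pachytene cells, and the Sertoli cell list at 9.28 ± 0.27 in type A and 6.37 ± 0.17 in spermatids.

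Between type A and type B spermatogonia no gene passed the test. Among genes for undifferentiated spermatogonia, which hold the stem cell pool, Zbtb16, Neurog3 and Upp1 read -1.09 ± 0.22, -0.76 ± 0.19 and -0.81 ± 0.24 log2 in type B against type A. Syce1 and Tex12, components of the synaptonemal complex that joins paired chromosomes, read 1.04 ± 0.21 and 1.03 ± 0.24. These 5 genes passed only when adjusted over the list alone, and they were chosen after their values were seen, as were the other 4 such genes. Those were Wt1 among Sertoli cell genes at -1.05 ± 0.23, Lum among peritubular, stromal and endothelial cell genes at 1.81 ± 0.27, and Lyz1 and Tyrobp among macrophage and blood cell genes at 1.55 ± 0.33 and 0.89 ± 0.23. Leaving out type B replicate 1, Zbtb16, Syce1, Lum, Lyz1 and Tyrobp passed over all genes (adjusted p = 0.02, 0.0067, 0.00861, 0.00619 and 0.0455). The limma test called 0 genes higher and 0 lower, with a smallest adjusted p of 0.339, and at an unadjusted p under 0.05 it gave 786 higher and 596 lower.

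As whole lists, undifferentiated spermatogonia had a median of -0.52 (adjusted p = 4.08e-05), the Sertoli cell list -0.52 (3.77e-06), the meiotic chromosome axis and recombination list 0.47 (6.72e-06), and macrophage and blood cell 0.57 (6.8e-05). For each of these the adjusted p = 0.482 with an estimated correlation. The undifferentiated median was -0.27 without type B replicate 2 (adjusted p = 0.00472), the Sertoli one -0.33 without type B replicate 1 (0.0342) and -0.80 without replicate 2 (7.87e-11), and the meiotic one 0.16 (0.367) and 0.81 (1.34e-16). The pachytene spermatocyte list stood at 1.29, spermatid acrosome and flagellum at 0.80, spermatid chromatin packaging at 1.01 and sperm-specific glycolysis at 0.65, with adjusted p = 0.482 to 0.538 with an estimated correlation. In the absence of type B replicate 2 these last 4 medians were 0.06, -0.10, 0.01 and 0.09, and their adjusted p 0.403, 0.124, 0.761 and 0.977. With type B replicate 1 left out the medians were 2.31, 1.61, 1.75 and 1.27, and 16, 23, 8 and 5 genes were higher. Leaving out type A replicate 2 gave adjusted p = 0.0824 for packaging and 0.0617 for sperm-specific glycolysis. Single members read 3.21 ± 1.70 for Ldhc, 2.02 ± 0.98 for the glycolytic kinase Pgk2, 1.98 ± 0.75 for the protamine Prm1 and 1.29 ± 0.55 for the chaperone Hspa2. Leaving out type B replicate 1 gave 1144 genes higher and 198 lower, among them Ldhc (adjusted p = 4.74e-06), Pgk2 (1.92e-05), Prm1 (9.19e-05) and Hspa2 (4.69e-04), and no other left-out array gave a call. The ribosomal protein list stood at 0.23 (adjusted p = 6.8e-05, and 0.555 with an estimated correlation), and at -0.10 when arrays were centred on those same genes, a setting that moved the median of all genes by -0.33. Its adjusted p was 0.134 after quantile normalization. The ribosomal median was 0.39 without type B replicate 1 (adjusted p = 1.39e-04) and 0.10 without replicate 2 (0.086).

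X-linked spermatid genes had a median of 0.51 (adjusted p = 0.025) and autosomal retrogenes of X-linked parents 0.21 (adjusted p = 0.00585), with adjusted p = 0.482 with an estimated correlation for both. The retrogene median was -0.12 with arrays centred on ribosomal protein genes, and the X-linked spermatid test gave 0.163 without type A replicate 2 and 0.332 without type B replicate 2, where the median was 0.17. Differentiating spermatogonia, DNA replication and mitosis, the piRNA pathway and sex body factors stood at -0.17, 0.13, 0.06 and 0.12 (adjusted p = 0.511, 0.123, 0.664 and 0.607), the last 3 at -0.20, -0.27 and -0.21 with that centring. X-linked housekeeping, X-linked spermatogonial and Y-linked genes read -0.02, 0.04 and -0.22 (adjusted p = 0.348, 0.788 and 0.347), the first 0.04 when centred on the 75th percentile and the second -0.06 after quantile normalization and -0.29 when centred on ribosomal protein genes. X-linked parents of retrogenes, somatic glycolysis and Leydig cell genes read 0.01, -0.15 and 0.61 (adjusted p = 0.759, 0.533 and 0.144), and peritubular, stromal and endothelial cell genes 0.07 (0.241). With ribosomal centring the parents stood at -0.32 and the stromal genes at -0.26, and the Leydig cell test gave 0.0373. The parents' median was -0.08 after quantile normalization. Left-out arrays brought further list tests under 0.05: type B replicate 1 for differentiating spermatogonia (0.0332), X-linked housekeeping (0.0266), X-linked spermatogonial (0.0312) and Y-linked genes (0.00907), type B replicate 2 for replication (1.23e-05), sex body factors (0.0349) and X-linked spermatogonial genes (3.21e-04), and type A replicate 2 for stromal genes (8.1e-04).

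From type B spermatogonia to pachytene spermatocytes, lists of spermatogonial, Sertoli, stromal and macrophage genes fell, and lists of pachytene, piRNA, and spermatid acrosome and flagellum genes rose, while the meiotic chromosome axis and Leydig cell lists did not pass as lists. The list calls were lost with an estimated correlation (adjusted p = 0.482 to 0.550). Stra8, the retinoic acid target needed to enter meiosis, fell by 3.43 ± 0.28 log2, as did the receptor Kit (-2.92 ± 0.25) and the retinoic acid binding protein Crabp1 (-3.89 ± 0.23). The collagens Col1a1 and Col3a1 of stromal cells fell, with values of -6.50 ± 0.24 and -5.23 ± 0.21. Adam3, a sperm surface protein, rose by 4.35 ± 0.98 (2.42 without type B replicate 1, adjusted p = 2.01e-04), and Piwil1, the Argonaute protein of pachytene piRNAs, by 3.71 ± 0.57. In all, limma called 3594 genes higher and 4573 lower, of which 2475 and 3434 changed at least 2-fold.

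Of the spermatogonial lists, 10 of 15 undifferentiated spermatogonia genes fell and 1 rose (the same counts adjusted over the list alone), with Zbtb16, a transcription factor of stem cells, at -2.19 ± 0.22. Of 13 differentiating spermatogonia genes, 11 fell and 1 rose, again the same adjusted over the list alone. Of 27 DNA replication and mitosis genes, 17 fell (18 adjusted over the list alone) and 3 rose; the replicative helicase subunits Mcm4 and Mcm5 fell (-3.95 ± 0.35 and -3.48 ± 0.23), and Mcm7 read 0.01 ± 0.18. The 3 list tests had adjusted p = 0.00429, 8.22e-04 and 0.00588, and adjusted p = 0.482, 0.482 and 0.55 with an estimated correlation. Without either pachytene array, 1 replication gene rose. Centring on the 75th percentile gave 13 replication genes lower and 6 higher, and centring on ribosomal protein genes 9 and 8, with a median of -0.12 against -1.22. For undifferentiated spermatogonia the last setting gave 5 lower and 3 higher.

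The meiotic chromosome axis and recombination list went both ways, with 7 of 26 higher and 7 lower, the same adjusted over the list alone (list test adjusted p = 0.568). Dmc1, the meiotic recombinase, fell by 3.21 ± 0.34 and Spo11, which makes the meiotic double-strand breaks, rose by 2.68 ± 0.21, while Sycp3 of the chromosome axis read 0.39 ± 0.28, or 0.83 without type B replicate 1 (adjusted p = 0.0115). Of 15 piRNA pathway genes, 11 rose and 1 fell, the same adjusted over the list alone, with Tdrd7 at 2.25 ± 0.28 (list test adjusted p = 0.00229, and adjusted p = 0.482 with an estimated correlation). Sex body factors, which mark the silenced XY chromatin, split into 4 higher and 4 lower of 19, the same adjusted over the list alone, with Mdc1 at 1.52 ± 0.25 and Brca1 at -2.35 ± 0.28 (list test adjusted p = 0.544). The meiotic list had 12 higher and the sex body factors 2 lower without type B replicate 1. Without pachytene replicate 1 the sex body factors had 1 higher, and without pachytene replicate 2 they had 2 lower. The sex body split was 10 higher and 2 lower when centred on the 75th percentile, and when centred on ribosomal protein genes it was 12 and 2, and that of the meiotic list 14 and 3.

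Genes of later germ cells were higher on the pachytene arrays as well. Purity of the preparations is not given, so whether the pachytene cells themselves expressed the spermatid genes was not tested. Of 23 pachytene spermatocyte genes, 18 rose (19 adjusted over the list alone) and 1 fell. Of 31 spermatid acrosome and flagellum genes, 27 rose (28 adjusted over the list alone) and none fell, with the acrosin-binding protein Acrbp at 3.52 ± 0.73. The list tests had adjusted p = 4.15e-05 and 6.72e-06, and adjusted p = 0.482 and 0.538 with an estimated correlation. Of 10 spermatid chromatin packaging genes, 5 rose, also adjusted over the list alone, with the testis bromodomain protein Brdt at 2.79 ± 0.33, the transition protein Tnp2 at 2.81 ± 0.76 and the protamine Prm1 at 1.59 ± 0.75 (adjusted p = 0.103). Type B replicate 2 held high values for these lists: without it, 30 acrosome and flagellum genes and 8 packaging genes rose, and the packaging list test, at adjusted p = 0.0629 with all arrays, gave 0.00111. With type B replicate 1 left out, 16 and 2 rose, without pachytene replicate 1, 7 and 1, and without pachytene replicate 2, 12 and 2. Without either type A or either spermatid array, 3 packaging genes rose, and with arrays centred on ribosomal protein genes 8. The call of Tnp2 was lost without pachytene replicate 1 (adjusted p = 0.059) or replicate 2 (0.0522), and Prm1 passed without type B replicate 2 (3.29e-05). Tnp2 read 1.35 without type B replicate 1 (0.00193) and 4.28 without replicate 2 (3.45e-06), and Acrbp 2.10 without replicate 1 (2.24e-04).

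Genes of sperm-specific glycolysis rose, and those of somatic glycolysis went both ways. Of 7 sperm-specific glycolysis genes, 6 rose and none fell, the same adjusted over the list alone (list test adjusted p = 0.00928, and adjusted p = 0.538 with an estimated correlation). The sperm enolase Eno4 rose by 2.32 ± 0.26, and Ldhc read 3.75 ± 1.70 (adjusted p = 0.0918), or 7.15 without type B replicate 2 (adjusted p = 5.25e-07). Leaving out type B replicate 1, 3 of these genes rose, without pachytene replicate 1, 1 rose, and without pachytene replicate 2, 3 rose. Of 12 somatic glycolysis genes, 4 rose and 6 fell, the same adjusted over the list alone (list test adjusted p = 0.788), with the phosphofructokinase Pfkp at 3.04 ± 0.30 and the hexokinase Hk2 at -1.62 ± 0.26. Their median was -0.65, and 0.45 with arrays centred on ribosomal protein genes, where 6 rose and 1 fell.

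X-linked genes fell against the rest of the genome. Of 477 X-linked genes, 332 fell and 14 rose (69.6% and 2.94%), against 31.1% and 26.1% of autosomal genes. The median X-linked log2 change minus the autosomal one was -1.51 (camera adjusted p = 1.29e-15, and adjusted p = 0.148 with an estimated correlation). It was -0.98 with a pseudocount of 64 and -0.94 with no filter. Timm17b, a mitochondrial import protein, fell by 4.22 ± 0.19, as did the germ cell homeobox gene Rhox13 (-4.40 ± 0.28) and Tex11, a meiotic recombination protein (-4.25 ± 0.31). The ribosomal protein gene Rps4x fell by 3.91 ± 0.26, below the -2.47 of the lowest of 42 autosomal ribosomal protein genes. Akap4 and Tsx went the other way, with Akap4, a flagellar scaffold protein, at 1.63 ± 0.40 and Tsx at 1.56 ± 0.30. The call of Akap4 was lost without pachytene replicate 1 (adjusted p = 0.0607).

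All X-linked gene groups but the spermatid list took part. Of 31 X-linked housekeeping genes, 29 fell and none rose, with a list median of -2.43, and of 15 X-linked spermatogonial genes, 13 fell and none rose. The demethylase Kdm5c, at -0.48 ± 0.29, was 1 of 2 housekeeping genes that did not pass. Of 8 X-linked spermatid genes, 1 rose and 1 fell (list test adjusted p = 0.468), and without type B replicate 2, 3 rose. Quantile normalization and centring on the 75th percentile gave 2 higher and 1 lower of these, and centring on ribosomal protein genes 7 and 1. All 6 Y-linked genes of the list fell, with Uba1y at -3.79 ± 0.28 and the translation factor Eif2s3y at -2.91 ± 0.26. These counts were the same adjusted over the list alone. With arrays centred on ribosomal protein genes, 11 X-linked spermatogonial genes fell and 2 rose, and 3 Y-linked genes fell. The housekeeping, spermatogonial and Y-linked list tests had adjusted p = 1.1e-10, 2.02e-05 and 0.00297, and adjusted p = 0.482 with an estimated correlation.

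Autosomal retrogenes, copies of X-linked parents, mostly moved against their parents. Of 8 X-linked parents, all 8 fell, and of 10 retrogenes, 7 rose and 1 fell, the same adjusted over the list alone. The glycolytic kinase Pgk1 fell by 2.39 ± 0.20 and its copy Pgk2 rose by 3.51 ± 0.98, the pyruvate dehydrogenase subunit Pdha1 fell by 2.44 ± 0.26 and Pdha2 rose by 2.84 ± 0.52, and the centrin Cetn2 fell by 3.24 ± 0.19 and Cetn1 rose by 4.11 ± 1.43. The sizes of these 3 rises depended on the type B arrays: Pgk2, Pdha2 and Cetn1 read 1.58, 1.87 and 1.28 without type B replicate 1 (adjusted p = 6.95e-04, 3.22e-04 and 0.00298), and Pgk2 and Cetn1 5.43 and 6.94 without replicate 2 (1.02e-06 and 6.49e-07). Rbmxl1 fell by 0.66 ± 0.18 and read 0.44 with arrays centred on ribosomal protein genes. The parents' list test had adjusted p = 6.8e-05 and the retrogenes' 0.048, and for both the adjusted p = 0.482 with an estimated correlation. Of the retrogenes, 8 rose and none fell when centred on the 75th percentile, and 9 rose and none fell when centred on ribosomal protein genes. Without pachytene replicate 1, 2 retrogenes rose (list test adjusted p = 0.0531), and without pachytene replicate 2, 4 (0.0528). The test of the autosomal retrogenes of X-linked parents gave 0.0535 and 0.0555 without type A replicate 1 and 2, 0.127 after quantile normalization, and 0.0579 and 0.0731 when arrays were centred on the 75th percentile or on ribosomal protein genes. Pgk2 lost its call without pachytene replicate 1 (adjusted p = 0.056) or 2 (0.0681), and Rbmxl1 likewise (0.0686 and 0.0709). Cetn1 lost it without any single type A, pachytene or spermatid array (0.0599 to 0.128).

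**Figure D2:**
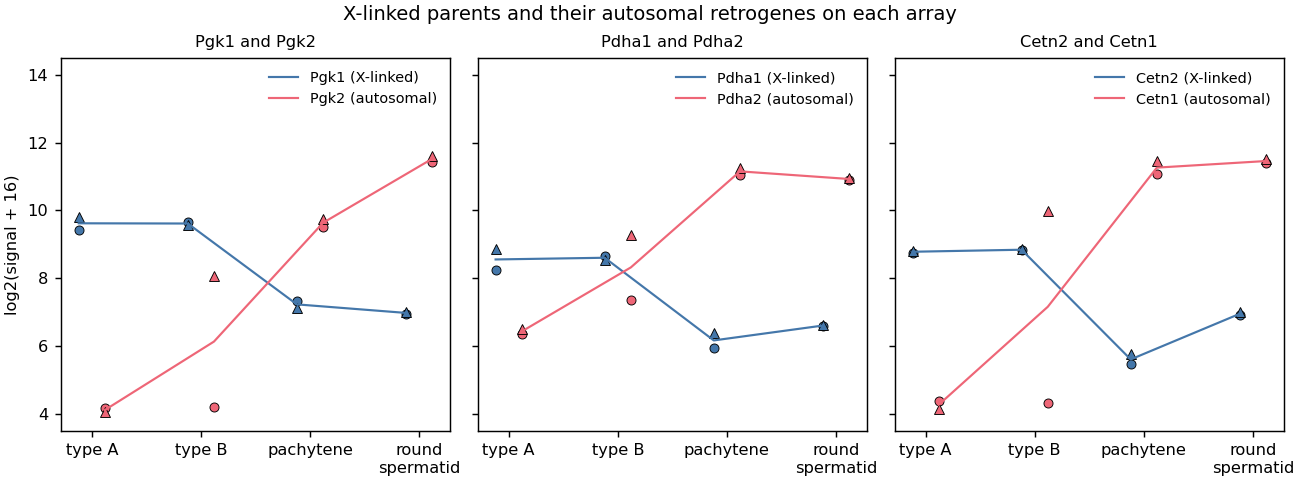
Log2(signal + 16) of 3 X-linked genes (blue) and their autosomal retrogenes (red) on each array by stage, with replicate 1 as circles, replicate 2 as triangles and lines through the means of 2 arrays. Pgk1 signal was 673.6 to 882.8 in spermatogonia and 106.2 to 144.8 later, and Pgk2 read 249.7 in type B replicate 2 and 2.4 in replicate 1.

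Genes of somatic testis cells fell in the same step. Of 17 Sertoli cell genes, 13 fell (14 adjusted over the list alone) and none rose, with the glutathione transferase Gstm6 at -2.28 ± 0.30 and the hormone Amh at -1.93 ± 0.38. Of 18 peritubular, stromal and endothelial cell genes, 14 fell, and of 11 macrophage and blood cell genes, 9 fell, the same adjusted over the list alone, with the lysozyme Lyz1 at -3.96 ± 0.33. Of 7 Leydig cell genes, 1 rose and 1 fell, the same adjusted over the list alone, with a median of -0.20 that became 0.10, 0.13 and 0.91 under quantile normalization and the 75th percentile and ribosomal centrings, and with the steroid enzyme Hsd3b1 at -2.30 ± 0.42. The Sertoli, stromal and macrophage list tests had adjusted p = 9.47e-04, 2.92e-05 and 0.00165, and adjusted p = 0.538, 0.482 and 0.482 with an estimated correlation, while the Leydig cell list gave 0.876. With arrays centred on ribosomal protein genes, the higher and lower counts were 2 and 3 for Sertoli, 4 and 1 for Leydig, 2 and 12 for stromal and 2 and 6 for macrophage genes. Of 42 autosomal ribosomal protein genes, 31 fell and none rose (32 and 1 adjusted over the list alone), with Rps19 at -2.47 ± 0.26 and Rpl14 at -2.39 ± 0.19, and without pachytene replicate 1, 19 fell. Their median was -0.98 (list test adjusted p = 2.02e-05, and adjusted p = 0.538 with an estimated correlation), and 0.13 with arrays centred on these same genes, where 6 rose and 7 fell.

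The split between higher and lower depended on the scaling. Centring on the 75th percentile gave 5023 higher and 3448 lower, a share higher of 59.3%, and centring on ribosomal protein genes gave 8211 higher and 1363 lower, 85.8%. These settings moved the median change of all genes, -0.07 as scaled by the authors, by 0.32 and 1.11, and quantile normalization moved it by 0.14.

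From pachytene spermatocytes to round spermatids, genes of the acrosome, the flagellum and chromatin packaging rose. Spam1 and Izumo1, sperm proteins of egg binding and fusion, rose by 4.26 ± 0.32 and 4.12 ± 0.29 log2, and the testis linker histone H1f7 by 4.40 ± 0.57. Lyzl1 had the largest rise of all genes called, 5.15 ± 0.45, and Tmem210 rose by 4.79 ± 0.18. Id4, an inhibitor of DNA-binding transcription factors, fell by 3.19 ± 0.28. In all, limma called 2219 genes higher and 2686 lower, of which 1748 and 1562 changed at least 2-fold. The count of lower genes was 1368 and 1499 without pachytene replicate 1 and 2, and 1662 and 1357 without spermatid replicate 1 and 2.

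Of 31 spermatid acrosome and flagellum genes, 22 rose (24 adjusted over the list alone) and none fell, with Spaca7 at 4.40 ± 0.31. Of 10 spermatid chromatin packaging genes, 8 rose, also adjusted over the list alone, where 1 fell. Tnp1, Tnp2, Prm1 and Prm2 rose by 3.79 ± 1.02, 3.53 ± 0.76, 3.09 ± 0.75 and 3.19 ± 0.76, the chromatin remodeller Chd5 by 2.10 ± 0.26, and Brdt read 0.17 ± 0.33. The ± of Tnp1 and Prm1 also holds the gap between their type B replicates. Calls lost below therefore do not measure the pachytene and spermatid arrays alone. Without pachytene replicate 1, spermatid replicate 1 or spermatid replicate 2 the packaging genes that rose numbered 5, 5 and 4. Tnp1 lost its call without any of the 4 pachytene and spermatid arrays (adjusted p = 0.0605 to 0.123), as did Prm1 (0.0542 to 0.089). Prm2 lost it without pachytene replicate 1 (0.0784) and spermatid replicates 1 and 2 (0.0588 and 0.0822), and Tnp2 without spermatid replicate 2 (0.0628). Of 7 sperm-specific glycolysis genes, 3 rose, the same adjusted over the list alone, with the aldolase Aldoart1 at 4.38 ± 0.31 and Gapdhs at 3.66 ± 0.46. The 3 list tests had adjusted p = 3.69e-11, 9.47e-04 and 0.00928, and adjusted p = 0.482, 0.482 and 0.538 with an estimated correlation.

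Genes of the pachytene and meiotic lists went both ways. Of 23 pachytene spermatocyte genes, 2 rose and 5 fell, the same adjusted over the list alone (list test adjusted p = 0.957), with the chaperone Calr3 at 3.12 ± 0.18 and the transcription factor Mybl1, a driver of pachytene piRNA genes, at -1.64 ± 0.27. Leaving out type B replicate 1 or 2, 6 of them rose and 6 fell, and without pachytene replicate 2 or spermatid replicate 2, 3 fell. Of 15 piRNA pathway genes, 6 fell and none rose, the same adjusted over the list alone (list test adjusted p = 0.0186, and adjusted p = 0.482 with an estimated correlation). Tdrd5 and Piwil1 fell (-2.58 ± 0.21 and -2.60 ± 0.57), while the helicase Ddx4 read 0.00 ± 0.22. Piwil1 lost its call without pachytene replicate 1 (adjusted p = 0.0546) and spermatid replicate 2 (0.0708). Of 26 meiotic chromosome axis and recombination genes, 4 rose and 4 fell, the same adjusted over the list alone (list test adjusted p = 0.957), with the meiotic cohesin Rec8 at 4.58 ± 0.33 and Dmc1 at 1.99 ± 0.34. Without type B replicate 1 or 2, 7 rose and 9 fell. Of 19 sex body factors, 2 rose and 6 fell (3 and 10 adjusted over the list alone; list test adjusted p = 0.223), with the histone methyltransferase Suv39h2 at 2.70 ± 0.25 and the kinase Atr at -1.52 ± 0.21. Without type B replicate 1 or 2, 10 fell, and without either pachytene array or spermatid replicate 2, 3 fell. With arrays centred on ribosomal protein genes, 2 sex body factors rose and 3 fell, and 5 and 3 meiotic genes.

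Some spermatogonial genes were higher in spermatids than in pachytene cells. Of 13 differentiating spermatogonia genes, 5 rose and 1 fell, the same adjusted over the list alone, with Crabp1 at 1.57 ± 0.23 and Kit at 1.28 ± 0.25 (list test adjusted p = 0.05, and adjusted p = 0.606 with an estimated correlation). That test lies at its threshold: it gave 0.0536 and 0.0557 without type A replicate 1 and 2, 0.0874 and 0.0501 without pachytene replicate 1 and 2, and 0.0957 without spermatid replicate 1. Without pachytene replicate 1, spermatid replicate 1 or spermatid replicate 2, 2 of the differentiating spermatogonia genes rose. None of them fell when centred on the 75th percentile (5 higher) or on ribosomal protein genes (4 higher). Of 15 undifferentiated spermatogonia genes, 2 fell and none rose (list test adjusted p = 0.788), and of 27 DNA replication and mitosis genes, 7 rose and 2 fell (list test adjusted p = 0.223), with Mcm2 at 1.81 ± 0.35; without spermatid replicate 2, 4 rose, and after quantile normalization 6 rose and 3 fell. Both counts were the same adjusted over the list alone. Of 12 somatic glycolysis genes, 4 rose and 1 fell (4 and 2 adjusted over the list alone; list test adjusted p = 0.483), with the hexokinase Hk1 at 1.79 ± 0.21. Without pachytene replicate 1 or spermatid replicate 2, 2 somatic glycolysis genes rose.

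X-linked genes rose against autosomal genes. Of 477 X-linked genes, 148 rose and 36 fell (31.0% and 7.55%), against 15.1% and 19.5% of autosomal genes. The X-linked minus autosomal change was 0.41 (camera adjusted p = 3.37e-07, and adjusted p = 0.240 with an estimated correlation). It was 0.23 with a pseudocount of 64, 0.24 with no filter and 0.74 with a filter at the 75th percentile, and 0.13 against autosomal genes matched on their type B and pachytene levels, 0.09 with spermatid replicate 1 and 0.21 with replicate 2. Of 8 X-linked spermatid genes, 7 rose, with Cypt1 at 4.47 ± 0.49 and Akap4 at 3.52 ± 0.40, and of 15 X-linked spermatogonial genes, 12 rose (13 adjusted over the list alone), with Rhox13 and Fthl17a both at 2.71, SE 0.28 and 0.24. Of 31 X-linked housekeeping genes, 10 rose and none fell, with Timm17b at 2.80 ± 0.19, while Rps4x and Pgk1 read -0.34 ± 0.26 and -0.25 ± 0.20. Among tested X-linked genes Tmem255a fell most, at -2.31 ± 0.22. Of 6 Y-linked genes, 4 rose (5 adjusted over the list alone), with Eif2s3y, Uba1y and Zfy2 at 2.96 ± 0.26, 2.51 ± 0.28 and 2.22 ± 0.38 and Kdm5d at 0.22 ± 0.23. The spermatid, spermatogonial, housekeeping and Y-linked list tests had adjusted p = 1.48e-04, 1.9e-06, 8.17e-04 and 0.00255, each with adjusted p = 0.482 with an estimated correlation. Counts not otherwise given were the same adjusted over the list alone.

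Of 8 X-linked parents, 3 rose, and of 10 retrogenes, 2 rose and 2 fell, the same adjusted over the list alone. The glucose 6-phosphate dehydrogenase copy G6pd2 rose by 3.22 ± 0.24 and the RNA cleavage factor copy Cstf2t fell by 1.45 ± 0.24. The list tests had adjusted p = 0.0423 and 0.41, the first with adjusted p = 0.499 with an estimated correlation. The test of the X-linked parents of retrogenes gave 0.0943 without pachytene replicate 1, 0.0526 without spermatid replicate 1 and 0.0657 with arrays centred on ribosomal protein genes.

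Somatic cell genes moved apart. Of 17 Sertoli cell genes, 11 fell (12 adjusted over the list alone) and none rose, with Clu at -2.30 ± 0.25 and the tight junction protein Cldn11 at -2.38 ± 0.22. Of 7 Leydig cell genes, 5 fell (6 adjusted over the list alone), with the steroid enzyme Cyp17a1 at -2.72 ± 0.36 and the cholesterol carrier Star at -1.89 ± 0.20. Of 11 macrophage and blood cell genes, 6 rose and none fell, the same adjusted over the list alone, with the lysozyme Lyz2 at 1.29 ± 0.19. Of 18 peritubular, stromal and endothelial cell genes, 3 rose and 1 fell (2 and 1 adjusted over the list alone; list test adjusted p = 0.71), with the proteoglycan Dcn at 2.01 ± 0.34 and Sparc at -1.99 ± 0.27. The Sertoli, Leydig and macrophage list tests had adjusted p = 7.57e-05, 0.00254 and 0.00484, and adjusted p = 0.495, 0.482 and 0.482 with an estimated correlation. Fewer Sertoli cell genes fell without pachytene replicate 2 (6) or spermatid replicate 1 (7), and 3 Leydig cell genes fell without pachytene replicate 2 or either spermatid array. The macrophage and blood cell genes that rose numbered 3 without either pachytene array and 2 without either spermatid array, and 1 stromal gene rose without pachytene replicate 1 or spermatid replicate 1. Of 42 autosomal ribosomal protein genes, the median was -0.02 (list test adjusted p = 0.957) and 0.05 with arrays centred on these same genes. The limma test called 0 of them, also adjusted over the list alone, and 1 at an unadjusted p under 0.05.

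Round spermatids set against type B spermatogonia show the net change across meiosis. Izumo3 and the transcription factor Spz1 rose by 6.46 ± 0.24 and 6.52 ± 0.66 log2, Odf1, a protein of the flagellar outer dense fibres, by 6.10 ± 0.73, and Tnp2 by 6.35 ± 0.76. The imprinted genes Plagl1 and Dlk1 fell (-5.91 ± 0.31 and -5.50 ± 0.24), as did the calcium-binding protein S100a10 (-5.48 ± 0.48). In all, limma called 3811 genes higher and 5709 lower, of which 2913 and 4226 changed at least 2-fold. Centring on the 75th percentile gave 5050 higher and 4129 lower (55.0% higher), and centring on ribosomal protein genes 7498 and 1267 (85.5%). They moved the median change of all genes, -0.27, by 0.38 and 1.17, and quantile normalization by 0.19.

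All 31 spermatid acrosome and flagellum genes rose, with the acrosomal membrane protein Spaca1 at 5.69 ± 0.28 and the mitochondrial capsule protein Smcp at 6.01 ± 1.02. Of 10 spermatid chromatin packaging genes, 9 rose and 1 fell, with Prm2 at 5.34 ± 0.76. Of 23 pachytene spermatocyte genes, 17 rose (20 adjusted over the list alone) and 1 fell, and of 7 sperm-specific glycolysis genes, 6 rose, with Aldoart1 at 5.54 ± 0.31 and Ldhc at 3.86 ± 1.70 (adjusted p = 0.0748). Ldhc read 7.26 without type B replicate 2 (adjusted p = 3.47e-07). The list tests had adjusted p = 1.3e-12, 4.91e-04, 5.47e-05 and 6.38e-04, each with adjusted p = 0.482 with an estimated correlation. The somatic glycolysis list went both ways, 5 higher and 5 lower of 12 (list test adjusted p = 0.636), with Hk1 at 3.19 ± 0.21 and Hk2 at -2.83 ± 0.26; without spermatid replicate 2, 3 rose, and with arrays centred on ribosomal protein genes 7 rose and 3 fell. Counts not otherwise given were the same adjusted over the list alone.

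Of 15 undifferentiated spermatogonia genes, 11 fell, with the stem cell factor Sall4 at -2.31 ± 0.35, and of 13 differentiating spermatogonia genes, 11 fell and 1 rose. The cyclin Ccnd2 fell by 2.91 ± 0.20 and Dmrtb1, a regulator of meiotic entry, rose by 2.25 ± 0.31. Of 27 DNA replication and mitosis genes, 14 fell and 2 rose, with Mcm4 at -2.50 ± 0.35, and their median of -0.73 became 0.45 with arrays centred on ribosomal protein genes, where 8 rose and 4 fell. That centring gave 5 lower and 2 higher for undifferentiated and also for differentiating spermatogonia. The 3 list tests had adjusted p = 0.00429, 0.0065 and 0.0271, and adjusted p = 0.482, 0.524 and 0.616 with an estimated correlation. The DNA replication and mitosis median was -1.15 without type B replicate 2 (adjusted p = 0.0059), and the test gave 0.057 without type B replicate 1 and 0.0984 with type A in place of type B, a comparison chosen after the data were seen. These counts were the same adjusted over the list alone.

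Meiotic, piRNA and sex body lists went both ways. Of 26 meiotic chromosome axis and recombination genes, 7 rose and 5 fell (6 and 3 adjusted over the list alone; list test adjusted p = 0.516), with Rec8 at 2.56 ± 0.33 and Tex12 at -1.66 ± 0.24. Their median of -0.18 became 0.21 when centred on the 75th percentile (9 higher, 1 lower) and 1.00 when centred on ribosomal protein genes (12 higher, none lower), and quantile normalization gave 5 higher and 3 lower. Their lower count was 3 without type B replicate 1 or either pachytene array, 11 without type B replicate 2 and 1 without either spermatid array, and 4 rose without spermatid replicate 1. Of 15 piRNA pathway genes, 5 rose and 5 fell (5 and 6 adjusted over the list alone; list test adjusted p = 0.523), with Tdrd7 at 2.87 ± 0.28 and Piwil4 at -1.78 ± 0.39, or -1.17 without type B replicate 1 (adjusted p = 0.00666). Without type B replicate 1, spermatid replicate 1 or spermatid replicate 2, 2, 3 and 1 of the piRNA pathway genes fell. The piRNA split was 4 higher and 3 lower after quantile normalization, 6 and 1 when centred on the 75th percentile, and 9 and 0 when centred on ribosomal protein genes. Of 19 sex body factors, 4 rose and 9 fell, the same adjusted over the list alone (list test adjusted p = 0.681), and 5 fell without type B replicate 1 and 4 without spermatid replicate 2. Their median of -0.50 became 0.67 with arrays centred on ribosomal protein genes (8 higher, none lower), and 5 were higher and 4 lower when centred on the 75th percentile, and 2 and 8 after quantile normalization.

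X-linked genes stayed below their premeiotic level. Of 477, 296 fell and 71 rose (62.1% and 14.9%), against 39.8% and 27.3% of autosomal genes, and the X-linked minus autosomal change was -1.01 (camera adjusted p = 6.05e-05, and adjusted p = 0.265 with an estimated correlation), or -0.63 with a pseudocount of 64 and -0.61 with no filter. Of 31 X-linked housekeeping genes, 26 fell, with the RNA helicase Ddx3x at -3.50 ± 0.32 and Rps4x at -4.25 ± 0.26, where the lowest autosomal ribosomal protein gene read -2.29. Of 15 X-linked spermatogonial genes, 12 fell and 2 rose, with Magea5 at -2.22 ± 0.26 and Fthl17a at 2.57 ± 0.24 (list test adjusted p = 0.0567). The X-linked spermatogonial test gave 0.00836 without type B replicate 2, 0.0267 after quantile normalization, and 0.0228 and 0.00575 when centred on the 75th percentile or on ribosomal protein genes. Of 8 X-linked spermatid genes, 6 rose and none fell, with Tsga8, Akap4 and Cypt1 at 5.71 ± 0.99, 5.15 ± 0.40 and 5.09 ± 0.49, and Tsga8 at 3.78 without type B replicate 1 (adjusted p = 1.95e-05). Of 6 Y-linked genes, 3 fell (list test adjusted p = 0.414), with Uty at -1.58 ± 0.27, Kdm5d at -1.37 ± 0.23 and Eif2s3y at 0.05 ± 0.26, and their median of -0.89 became 0.28 with arrays centred on ribosomal protein genes. Of the 8 parents, 7 fell, with Pgk1 at -2.64 ± 0.20, while Utp14a read -0.24 ± 0.21, or 0.93 with that centring. Of 10 retrogenes, 7 rose and 1 fell, with Pgk2 at 5.40 ± 0.98 (3.47 without type B replicate 1, adjusted p = 1.11e-05) and G6pd2 at 4.16 ± 0.24, and their test gave 0.134 after quantile normalization and 0.0567 and 0.0871 under these centrings. With arrays centred on ribosomal protein genes, the higher and lower counts were 3 and 14 for X-linked housekeeping, 2 and 2 for X-linked spermatogonial, 2 and 0 for Y-linked genes and 1 and 5 for the parents. The housekeeping, spermatid, parent and retrogene list tests had adjusted p = 1.13e-05, 0.00463, 0.00429 and 0.0405, each with adjusted p = 0.482 with an estimated correlation. These counts were the same adjusted over the list alone.

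Somatic cell genes were lower in spermatids. All 17 Sertoli cell genes fell, with the inhibin subunit Inhbb at -3.19 ± 0.24 and Gstm6 at -3.63 ± 0.30. Of 18 peritubular, stromal and endothelial cell genes, 14 fell, with Col1a1 at -5.43 ± 0.24, and of 7 Leydig cell genes, 5 fell, with Hsd3b1 at -3.90 ± 0.42. Of 11 macrophage and blood cell genes, 7 fell (list test adjusted p = 0.115), 4 without spermatid replicate 2, and their median of -0.71 became 0.46 with arrays centred on ribosomal protein genes (4 higher, 2 lower). After quantile normalization or centring on the 75th percentile, 3 of them fell. Stromal genes split into 3 higher and 13 lower with the ribosomal centring. The Sertoli, stromal and Leydig list tests had adjusted p = 2.02e-05, 1.49e-04 and 0.0406, each with adjusted p = 0.482 with an estimated correlation. The Leydig cell test gave 0.151 without type B replicate 2, and without spermatid replicate 1 it gave 0.0526. Of 42 autosomal ribosomal protein genes, 31 fell, with Rpl14 at -2.29 ± 0.19 (list test adjusted p = 2.09e-04, and adjusted p = 0.589 with an estimated correlation), and their median of -1.06 became 0.11 when centred on these same genes (9 higher, 3 lower). These counts were the same adjusted over the list alone.

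Taking the stages together, the median X-linked level was divided by that of autosomal genes, each with the pseudocount added to the signal. This ratio was 108% in type A, 96.0% in type B, 43.7% in pachytene cells and 60.7% in spermatids. On the log2 scale it was 0.11 ± 0.04, -0.06 ± 0.11, -1.19 ± 0.10 and -0.72 ± 0.10 (SD, n = 2). The pseudocount makes up more of a low signal. The 43.7% and 60.7% are therefore higher than ratios of the signal itself would be. The stages differed by an exact permutation test with p = 0.00952, the smallest this design can give. Of 477 X-linked genes, 13 had their highest mean in pachytene cells (2.73%, against 24.9% of autosomal genes), and 224 had it in type A. Between type A and type B the X-linked minus autosomal change was -0.07 (camera adjusted p = 0.0354, and adjusted p = 0.472 with an estimated correlation). It was -0.08 without type A replicate 2 (adjusted p = 0.152) and -0.0016 without type B replicate 2 (0.992). The 8 Y-linked genes tested had a median change against autosomal genes of -1.95 from type B to pachytene cells and of 1.38 in the next step. No autosome moved by more than 0.11 against the others from type B to pachytene cells.

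**Figure D3:**
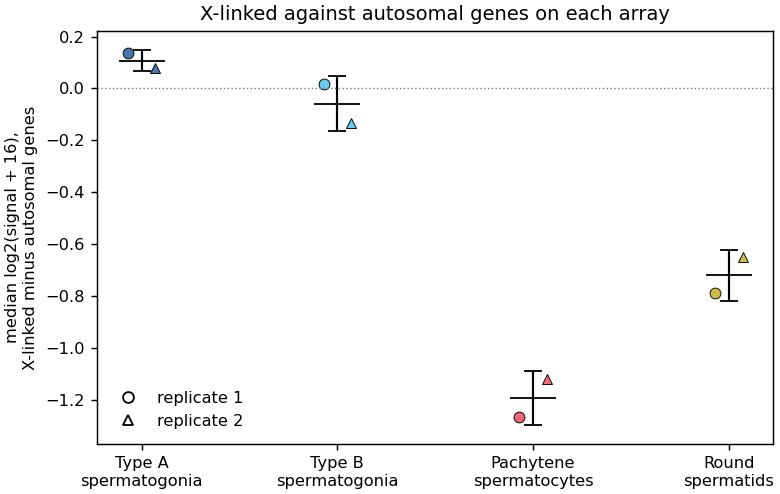
Median log2(signal + 16) of X-linked genes minus that of autosomal genes on each of 8 arrays, by stage, with replicate 1 as circles, replicate 2 as triangles, and the bar and whiskers the mean ± SD of 2 arrays. Both pachytene arrays (-1.27 and -1.12) and both spermatid arrays (-0.79 and -0.65) lie below all 4 spermatogonial arrays.

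**Figure D4:**
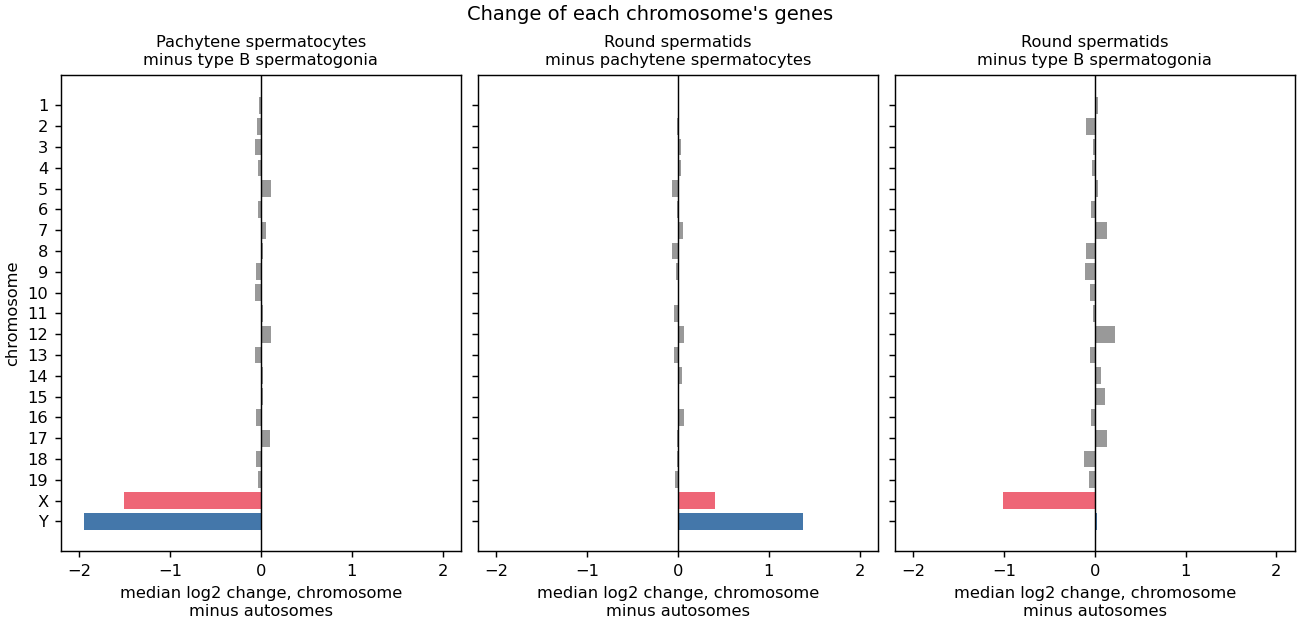
Median log2 change of the genes of each chromosome minus that of the other autosomes, or of all autosomes for X and Y, in 3 comparisons, with autosomes in grey, X in red and Y in blue. X stands at -1.51, 0.41 and -1.01 from left to right, and no autosome is beyond 0.23 in size.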

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

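Type A in place of type B and the crossed replicate block were tests chosen after the results were seen. The counts of called genes stayed within 1.5 times their value in 170 of 188 combinations of count and setting. Centred on ribosomal protein genes, they were 8211 higher and 1363 lower from type B to pachytene cells, 1614 lower from pachytene cells to spermatids, and 7498 and 1267 from type B cells to spermatids; moving every array by those genes shifts all changes alike. With every probe set tested they were 5805 and 8431, 3360 and 4504, and 5999 and 10670, as more features were tested. With at least 2-fold change required, 1562 were lower from pachytene cells to spermatids. Leaving out each array in turn, where a stage with 1 array left is assumed to vary like the others, gave for type B against type A 0 to 1144 higher and 0 to 198 lower, both highest without type B replicate 1. For pachytene against type B it gave 2530 to 3585 and 3639 to 4747, for spermatids against pachytene 1553 to 2674 and 1357 to 3330, and for spermatids against type B 3063 to 3790 and 4743 to 5781.

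The X-linked minus autosomal change kept its sign and its call in 92 of 98 combinations. The exceptions were all in type B against type A: -0.0416 with no filter, -0.0339 with the mean of all probe sets, -0.0604 with every probe set and -0.0393 against autosomal genes matched on level (adjusted p from 0.057 to 0.196), and with an array left out it ran from -0.106 to -0.0016. The cause was not tested. Pseudocount and filter changed its size: over all settings with all arrays it was -2.08 to -0.94 from type B to pachytene cells, 0.23 to 0.74 from pachytene cells to spermatids and -1.40 to -0.61 from type B cells to spermatids. With 1 array left out the change was -1.63 to -1.41 from type B to pachytene cells, 0.37 to 0.49 from pachytene cells to spermatids and -1.12 to -0.84 from type B cells to spermatids, and the permutation p of the X-linked level was 0.00952 to 0.0190. Of the 88 list tests 55 were called, and 51 to 57 with an array left out.

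In 1980 combinations of list and setting, 1898 kept their side of the threshold, 57 lost the call, 22 gained it and 3 reversed with a call in at least 1 setting. The direction of the camera test turned in 51 others, called in neither setting, and the sign of the median turned in 80, of which 6 were among 1241 combinations of called lists. The reversed ones were in type B against type A: spermatid acrosome and flagellum at -0.10 without type B replicate 2 (range -0.10 to 1.61), sperm-specific glycolysis at 0.0945 (0.0945 to 1.27), where the test direction, not the median, turned (adjusted p = 0.977), and X-linked spermatogonial genes at -0.40 without type B replicate 1 (to 0.48). Of 3192 combinations for named genes, 3116 kept their side of the threshold, 18 of them with a turned sign and no call, 50 lost the call, 24 gained it and 2 reversed, both when centred on ribosomal protein genes: Rbmxl1 at 0.44 from type B to pachytene cells (adjusted p = 0.186) and Utp14a at 0.93 from type B cells to spermatids (0.0191).

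With type A in place of type B, 3834 genes were higher and 5002 lower in pachytene cells, and 3955 and 5886 in spermatids; 7587 of 8167 and 8847 of 9520 called genes were shared in the same direction. With the replicate number as a block the counts were 3564 and 4584, 2205 and 2660, and 3779 and 5686 in the 3 later comparisons. The numbers do not pair the samples: correlations of replicate deviations between stages were -0.178 to 0.173. Crossing the type B replicates in that block gave 3523 and 4543, 2195 and 2599, and 3801 and 5693 calls. Low signals near the background of the array are compressed on the log2(signal + 16) scale, which limits what is seen for weak genes.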

Other observations

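The tests of imprinted genes, later-stage genes, meiotic entry, labels, scaling, lost cells, the signal floor and a few spermatid genes were chosen after the results were seen, and the lists of imprinted and axoneme genes were written after the data were seen.

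Imprinted genes, which are expressed from a single parental copy, fell together. Of 18 tested, 15 were lower and 2 higher in round spermatids than in type B spermatogonia, and 15 were lower in pachytene cells. Between type B cells and spermatids the growth factor Igf2 changed by -3.13, Ndn by -4.60, Peg3 by -3.69, Mest by -2.56 and Gnas by -2.97, while Asb4 rose by 3.06 and Rasgrf1 by 1.81 and Magel2 read -0.56, or -0.85 without type B replicate 1 (adjusted p = 0.0165). The camera test of the list gave p = 0.0002372, and p = 0.0391 with an estimated correlation. The camera p-values of this list and of the axoneme list below are unadjusted, unlike those of the lists fixed earlier. Some of the earlier lists had an unadjusted p as small with an estimated correlation. X-linked spermatid genes from pachytene cells to spermatids, for example, gave 0.0209 with camera before adjustment. Without Dlk1, Plagl1 and Igf2, whose falls had drawn attention to the list, 12 of 15 were lower (p = 0.00350, and 0.0404 with an estimated correlation). The list shares 1 gene with the stromal cell list, whose genes fell as well, so loss of somatic cells and of spermatogonia remains open.

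Axoneme and intraflagellar transport genes, which build the core of the sperm tail, were higher on the pachytene arrays as well as in spermatids. Of 33 tested, 31 were higher there than in type B spermatogonia and 27 were higher in spermatids, with Tekt4, Tekt2 and Dnaic2 at 4.92, 4.41 and 4.52 in spermatids against type B. The camera test for pachytene cells against type B gave p = 2.90e-10, and p = 0.177 with an estimated correlation, and that for spermatids against type B p = 8.112e-08, and 0.236. The list median was 2.99 in the first and 3.23 in the second, and 1.86 and 2.09 without type B replicate 1. Between type A and type B it was 0.80, with 0 genes called by limma (camera p = 1.46e-09, and 0.191 with an estimated correlation), 2.02 with 24 genes called higher without type B replicate 1, and -0.0052 without type B replicate 2 (p = 0.752). From pachytene cells to spermatids 4 rose and 6 fell, 8 and 9 without either type B array, and 0 or 1 rose and 1 to 3 fell without any single pachytene or spermatid array. Ift88 rose by 0.75, Ift20 read -0.50, or -0.74 without type B replicate 1 (adjusted p = 0.0160), and Ift81 read -0.41. None of these genes was in a list fixed earlier.

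Type B replicate 2 read at least 2-fold higher than replicate 1 for 92.11% of 634 genes that are high in later stages, against 3.58% of other autosomal genes. An exchange of labels with a pachytene or spermatid array is argued against, since replicate 2 correlates with replicate 1 higher, by 0.1609, than with any of those, but an exchange among type A and B arrays stays open: replicate 1 correlates at 0.957 and 0.975 with the type A arrays, and 8 of 22 lists, such as macrophage and blood cell (6.87 and 6.48 in type A, 7.26 and 7.36 in type B), did not overlap between the types, against a share of 0.333 by chance. Cells nearer to meiotic entry, with no later cells, are argued against too, since the meiotic list differed by -0.75 and the chromatin packaging list by 1.78, a gap of -2.53. A candidate explanation is some later-stage cells in that preparation: the excess of replicate 2 was 21.1% of the pachytene excess at the median, with quartiles of 16.2 and 27.9%. Whether the animals or the purification differed was not tested.

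From type B to pachytene cells the X-linked minus autosomal log2 change was -1.51. The change was -1.386 after quantile normalization. That normalization keeps the order of genes within an array, and a factor common to an array nearly cancels in the measure. The test was therefore bound to leave a fall and cannot decide on scaling. X-linked genes fell by more than autosomal genes matched on their level in types A and B, with a median difference of -1.351. Of X-linked genes, 92.7% lay below their matched mean. The bootstrap interval of -1.51 to -1.23 is over genes, which are not independent replicates, and holds no spread between preparations. The match left out how far a gene is confined to spermatogonia or somatic cells. It therefore cannot decide how much of the fall comes from fewer such cells. A labelling or hybridization difference would coincide with the stages and stays open, though no autosome moved by more than 0.11 against the others. Housekeeping genes are not confined to such cells, yet 29 of 31 X-linked ones fell and none rose. Their median was -2.43, against -0.04 for all autosomal genes and -0.98 for autosomal ribosomal protein genes. For these 31 genes this argues against fewer spermatogonia and somatic cells as the whole cause. For the other X-linked genes the part of such cells stays open, and silencing of the X chromosome in meiosis remains a hypothesis. The comparison was planned, but the tests of scaling and of lost cells were not.

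X-linked genes rose by 0.41 against autosomal genes from pachytene cells to spermatids. A few spermatid genes are argued against as the whole cause, since among genes above the median on both type A arrays 69 of 231 X-linked genes were called higher, 29.9% against 9.87% of autosomal ones, a difference of 20 points. These autosomal genes were not matched on their pachytene level. The size of that difference therefore cannot be read as a shift of the chromosome. With a pseudocount of 64, 0.2345 was left. A larger pseudocount shrinks changes near the floor of the scale but does not remove them, so this cannot decide on the floor. Spermatogonia and somatic cells in the spermatid preparation, or the floor of the scale, may account for part. Autosomal genes matched on their type B and pachytene levels rose as well, by 0.25 at the median against 0.33 for X-linked genes. The median rise over the matched genes was 0.1297 (0.0859 with spermatid replicate 1 and 0.209 with replicate 2), with 57.4% of X-linked genes above their matched mean. The bootstrap interval of 0.04 to 0.23 is over genes and holds no spread between preparations. The lists of such cells moved apart in this step, with medians of 0.53 for differentiating and -0.05 for undifferentiated spermatogonia, 0.68 for macrophage and blood cell, 0.11 for stromal, -1.30 for Sertoli and -1.86 for Leydig cell genes. Whether any of the rise is release of silencing stays open.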
